A study of Drosophila melanogaster with 4 samples.

How the data were processed

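Chromatin of Oregon-R embryos was crosslinked with formaldehyde and immunoprecipitated with an antibody against H3K36me1, and input chromatin was sequenced as background, per the labels' protocols. Reads were mapped with Bowtie 0.12.7, per the submitters' processing notes. Each immunoprecipitated replicate has 1 list of regions of significant enrichment, called with its own input sample per the labels, and 1 list covers the set of replicates. Positions are those of FlyBase release 5, per the file headers, which name 14 sequences with a total of 168.7 Mb. The program that called the regions, its threshold, the fragment length and the way in which the replicates were combined are not given in the sources used here. The deposited value of each region is a score, and its scale is not given in the sources used here.

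The scale was examined from the scores themselves. If scores are logarithms of a constant times a ratio of whole numbers, then the base raised to the difference of a pair of scores is itself such a ratio. With base 2 and a constant chosen to give the smallest whole numbers, 99.6% of the scores of replicate 1, 99.9% of those of replicate 2 and 99.3% of those of the set were ratios with a denominator of at most 5000, within a relative tolerance of 1e-10. Against the most frequent score of each list, with a denominator of at most 1000 and no such choice, base 2 gave 51.0%, 82.7% and 33.5%. Base e gave 0.294%, 0.553% and 0.273%, and base 10 gave 0.313%, 0.509% and 0.273%. Scores are therefore described as log2 ratios. The constants differ between lists, so levels of score are compared within a list and not between lists. No read numbers were derived from the scores, so the depth is unknown and no counting interval is given.

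Regions are given from 1, both ends included, as in the files. Regions common to both replicates are the overlaps of their regions (4301 intervals). The overlap of the replicates was tested with 1000 circular shifts of replicate 2 within each chromosome, one-sided. Coverage of X relative to 2L, 2R, 3L and 3R was given a 95% interval from 2000 bootstrap draws of 1 Mb blocks within arms, and that of chromosome 4 and of the heterochromatic scaffolds from 250 kb blocks. Chromosome 4 was also set against 1826 windows of its length, 1.35 Mb, placed every 50 kb on the autosomal arms. Medians of scores were given intervals from 1000 draws of 1 Mb blocks. The scaffolds U and Uextra, which have no known place, entered the totals and not the chromosome comparison. No test across samples was run, since an exact test on 2 replicates of 1 condition cannot reach 0.05. Such shifts and draws describe these region lists. They do not measure the spread between embryo collections.

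The tests, the alternatives and the rule for regions to be named were fixed before the data were examined, except where stated. That rule named the 10 shared regions with the highest mean rank of score if the annotation was not of the build of the files. The shift tests of overlap by single chromosome and by region length were not among the tests fixed beforehand. The gene table at hand is of release 6, so no gene was assigned to a region. The planned tests of promoters, exons and introns, of position along genes, of gene length and of 26 gene lists, with all their alternatives, were therefore not run. The alternatives that were run were the higher-scoring 50% of each list, merging of regions less than 1000 bp apart, a reciprocal overlap of 50%, random placement in place of shifts, smaller blocks, the list for the set of replicates, regions in either replicate, and each replicate alone.

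The code was tested on simulated data. With 60.5% of the 5434 regions of replicate 1 kept in place and the others moved at random, 65.6% were found to overlap, since moved regions also overlap by chance. Among 100 lists made by shifting the 4523 regions of replicate 2 at random, 4 passed a threshold of 0.05. These lists were ranked against further shifts made in the same way, so a share near the threshold was fixed in advance. This checks the code and not whether shifts are a fair comparison for real lists. With the intervals on X thinned to 0.7 among the 4301 shared intervals of all chromosomes, the mean estimate was 0.702 and 50 of 50 intervals held the planted ratio. This simulation varies by thinning alone and does not test the width of the intervals. Scores of the 5279 regions of replicate 1 on the large arms were also shuffled, and 0.1 was added on X. The mean difference found was 0.10, and 47 of 50 intervals held the added 0.1. Shuffling removes any likeness of neighbouring regions, so the width of the intervals on the real scores was not tested. Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.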

Results

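H3K36me1, the monomethylated form of lysine 36 of histone H3, was mapped by chromatin immunoprecipitation and sequencing in wild-type Oregon-R embryos of Drosophila melanogaster aged 14 to 16 hours, the late part of embryogenesis when organs differentiate. The series holds 4 samples. They are 2 immunoprecipitated replicates and 2 input samples, which are sheared chromatin sequenced without the antibody. Each replicate has a deposited list of regions enriched over its input, and a further list covers the set of replicates. The input samples served as the background of these lists and have no values of their own here. The lists give positions on FlyBase release 5 and a score per region, and read numbers were not used here, so the sequencing depth behind a region is unknown. With 1 stage, 1 genotype and 1 antibody, the comparisons that the design allows are enrichment over input, the agreement of the replicates, and the places in the genome where the enriched regions lie. The labels do not say whether the replicates came from separate embryo collections, so the spread between them may be technical.

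H3K36me1-enriched regions were mostly short, and a minority of broad domains held a large part of the enriched sequence. Replicate 1 had 5434 regions that covered 23.3 Mb, or 19.1% of the 5 large arms (2L, 2R, 3L, 3R and X). Replicate 2 had 4523 regions that covered 20.0 Mb, or 16.4% of these arms. The median region was 2212 bp long in replicate 1 and 2258 bp in replicate 2. Regions of at least 10 kb numbered 439 in replicate 1 and 388 in replicate 2. They made up 8.08% and 8.58% of the regions, and they held 38.4% and 39.7% of the covered length. Broader regions carried higher scores, with a Spearman correlation across regions of 0.796 in replicate 1 and 0.780 in replicate 2. In the list for the set of replicates it was lower by value, at 0.586. How the score of a region was formed is not known here, so whether length enters it by definition was not tested. Regions are not independent replicates, so no p-value is attached to these correlations.

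The replicates marked largely the same sequence. Together they shared 17.8 Mb, and the shared length was 0.699 of the length in either list (Jaccard index). Circular shifts of replicate 2 along each chromosome gave a mean index of 0.0982 and a highest of 0.197 over 1000 shifts. The one-sided permutation p was therefore 0.001, the smallest that this number of shifts can give. Of the regions of replicate 1, 3725 (68.5%) overlapped replicate 2 by at least 1 bp, against 25.9% on average after shifting. Of the regions of replicate 2, 3898 (86.2%) overlapped replicate 1, against 30.4% after shifting. The index was 0.707 on 2L, 0.671 on 2R, 0.709 on 3L, 0.731 on 3R, 0.686 on X and 0.615 on chromosome 4. Each lay above all 1000 shifts of its own chromosome (one-sided permutation p = 0.001), which reached at most 0.377 on the large arms, on 3R. On chromosome 4 the shifts had a mean of 0.166 and a highest of 0.611, close to the observed value. On the heterochromatic scaffolds, with 47 and 35 regions, it was lower by value, at 0.369. Across the 117 full windows of 1 Mb on the large arms, the covered shares of both replicates had a Pearson correlation of 0.987 and a Spearman correlation of 0.977. These describe windows within 1 pair of samples and carry no p-value.

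The overlap was also taken by region length. All 439 regions of at least 10 kb in replicate 1 and all 388 in replicate 2 overlapped the other replicate, against 45.8% and 50.8% after shifting. Replicate 2 contained 95.8% of the length of the long regions of replicate 1. Of the regions of 2 to 5 kb, 82.7% of those in replicate 1 and 94.7% of those in replicate 2 were matched. Of the regions under 2 kb, 38.6% of 2154 in replicate 1 and 70.1% of 1769 in replicate 2 were matched. The shifted means for these short regions were 21.3% and 24.97%. In each of these length classes the observed share lay above every one of the 1000 shifts (one-sided permutation p = 0.001). Regions found in replicate 1 alone numbered 1709 and had a median length of 1664 bp and a median score of 0.53, against 3006 bp and 0.68 for the matched ones. Regions found in replicate 2 alone numbered 625, with a median of 1533 bp and a score of 0.64, against 2564 bp and 0.74 for the matched ones.

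**Figure D1:**
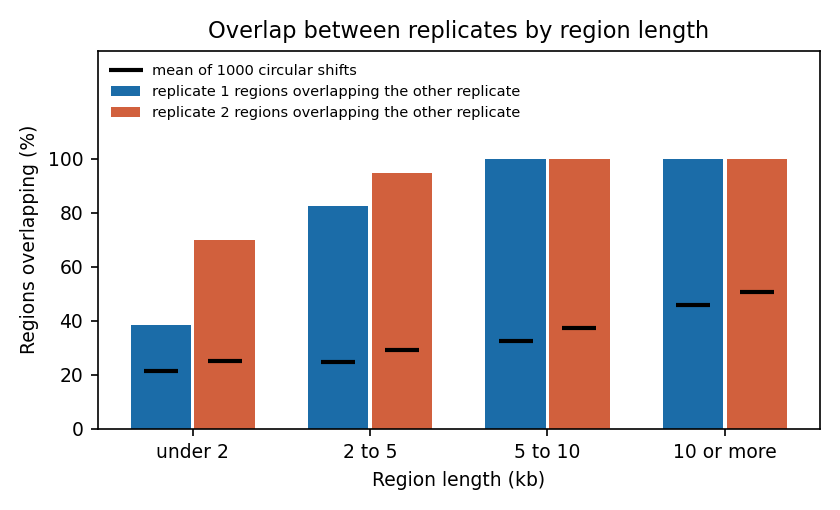
Bars give the percent of regions of each replicate that overlapped the other replicate by at least 1 bp, by region length in kb, and black marks give the mean of 1000 circular shifts. Regions of 10 kb or more overlapped in every case, while those under 2 kb overlapped in 38.6% of cases in replicate 1 and 70.1% in replicate 2.

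Scores of overlapping regions ranked alike in both replicates. Over 4301 overlapping pairs the Spearman correlation across regions was 0.701, with a 95% interval of 0.680 to 0.721 from resampling 1 Mb blocks. The correlation was 0.821 over the 3011 pairs that overlapped by at least 50% of both regions. The 10 regions with the highest mean rank of score in both replicates lay on 5 arms. The first lay on 2R from 15141791 to 15166593, 24.8 kb long, with a score of 2.35 in replicate 1 and 2.25 in replicate 2. The second lay on 2L from 161704 to 185269, with scores of 2.20 and 2.22. A region on 3R from 27521114 to 27539244 scored 2.16 and 2.11, and one on 3R from 25078308 to 25139351, 61.0 kb long, scored 2.16 and 2.10. A 7.30 kb region on 3L from 7972182 to 7979477 scored 2.23 and 2.00. A 40.0 kb region on 3R from 913251 to 953222 scored 1.99 and 2.01. A second region on 2L, from 21023075 to 21042146, scored 1.99 and 2.00. The X chromosome held 3 of the 10. A pair of neighbours on X, from 12608254 to 12628711 and from 12631198 to 12644851, scored 1.98 and 2.03, and 1.94 and 2.01. The remaining X region, from 6762458 to 6772190, scored 1.99 and 1.93.

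The broadest domains were called in both replicates, with lengths that differed at some sites (sites chosen after their values were seen). The longest shared interval was 167.7 kb, on 3R from 6331465 to 6499119, within a region of 168.2 kb in replicate 1 and 170.8 kb in replicate 2. The next were 136.0 kb on 2L from 21773983 to 21909974, 107.7 kb on 3R from 2738278 to 2846024 and 92.3 kb on 3R from 12490772 to 12583042. The region at 2738278 on 3R was 134.9 kb long in replicate 1 and 107.7 kb in replicate 2. An interval of 82.2 kb on 3L from 11360307 to 11442499 followed. The longest X interval was 62.1 kb, from 3237751 to 3299803. In windows of 250 kb, the window on 3R from 12500001 to 12750000 was covered to 91.4% in replicate 1 and 91.5% in replicate 2. The window on 3L from 11250001 to 11500000 was covered to 79.4% and 78.0%. The median window was covered to 17.4% in replicate 1 and 14.5% in replicate 2. Of 474 full windows, 10 were covered to more than 50% in both replicates and 8 held no region in either.

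**Figure D2:**
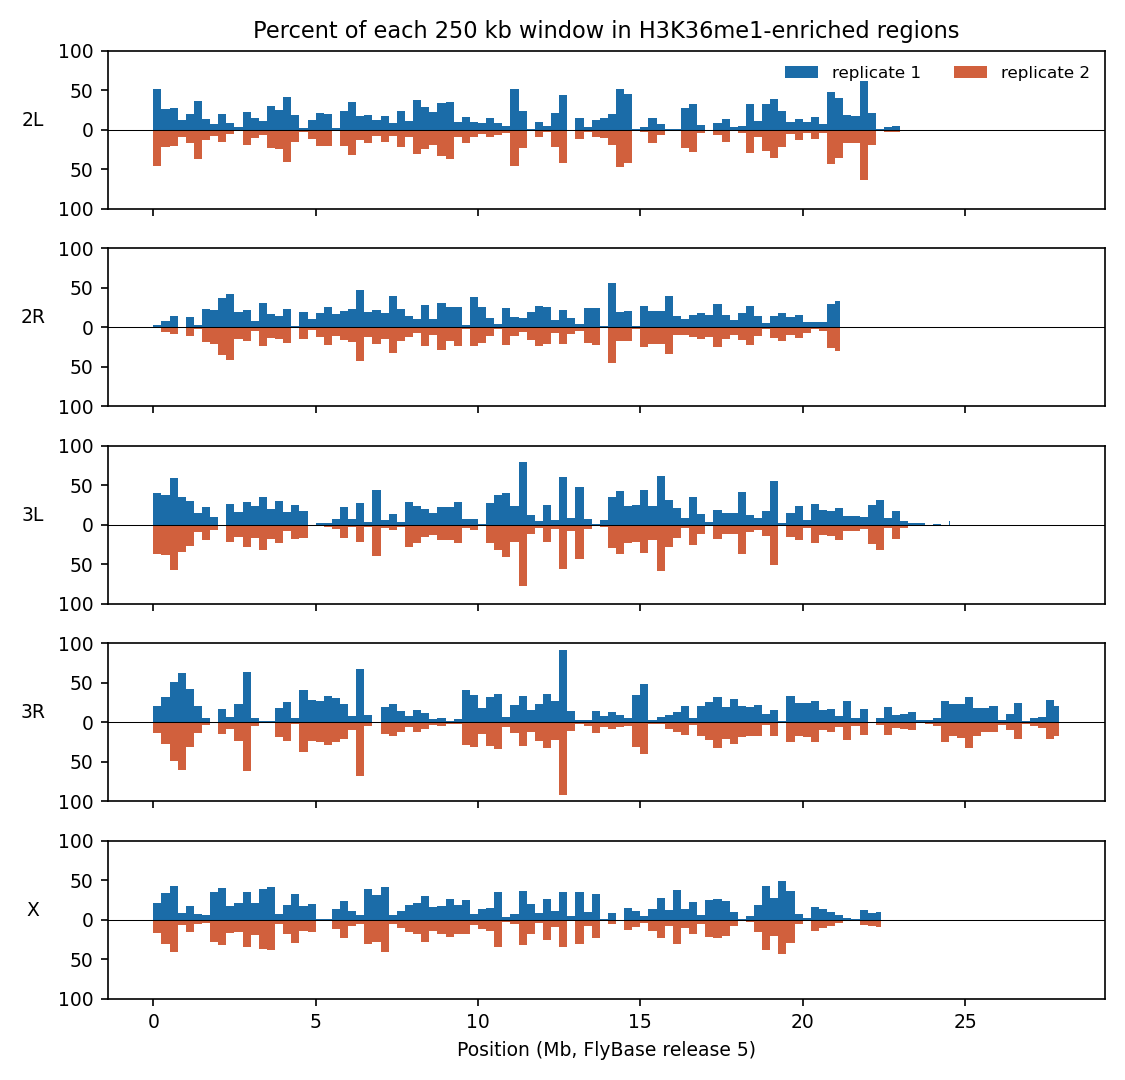
Each panel is a chromosome arm, with position in Mb on FlyBase release 5 along the x axis and the percent of each 250 kb window in enriched regions on the y axis, replicate 1 upward and replicate 2 downward. The profiles mirror each other, and the tallest window, on 3R from 12500001, was covered to 91.4% in replicate 1 and 91.5% in replicate 2.

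Enriched sequence had similar shares on the 5 large arms, a higher value on chromosome 4, and a far lower share on the heterochromatic scaffolds. The share of sequence in regions common to both replicates was 14.4% on 2L, 13.7% on 2R, 15.8% on 3L, 15.1% on 3R and 14.1% on X. The X chromosome, present as a single copy in males, was covered 0.949 times as much as the autosomal arms, and the 95% block bootstrap interval of 0.788 to 1.12 held 1. In single replicates the X was covered to 18.6% and 15.9%, against 19.2% and 16.5% for the autosomal arms.

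On chromosome 4, the small dot chromosome that is largely heterochromatic and still carries genes, 31.0% of the sequence was enriched in replicate 1 and 26.2% in replicate 2. Regions common to both replicates covered 21.8% of it, which was 1.47 times the share of the autosomal arms. The 95% interval from 250 kb blocks was 1.00 to 1.97, its lower end just above 1. Chromosome 4 holds few such blocks, so this interval may be too narrow. Its lower end is therefore no firm sign of a ratio above 1. The interval was 1.20 to 1.97 in replicate 1 alone and 1.11 to 2.07 in replicate 2 alone. It was 1.29 to 2.07 for regions in either replicate, 1.32 to 1.94 in the set list and 1.02 to 1.95 with merging. These rest on the same few blocks, and the interval with the higher-scoring 50%, given below, held 1. Of 1826 windows of the same length on the autosomal arms, 199 (10.9%) were covered as much by the common regions. The number of windows covered as much as chromosome 4 depended on the list and was 49 (2.68%) for the list for the set of replicates, 75 (4.11%) for regions in either replicate, 99 (5.42%) in replicate 1 alone, 117 (6.41%) in replicate 2 alone and 190 (10.4%) with regions less than 1000 bp apart merged. Without the 10% of each autosomal arm nearest the centromere, a setting added after the data were examined, it was 155 of 1633 windows (9.49%) for the common regions. With the higher-scoring 50% of each list 638 windows (34.9%) were covered as much, the ratio was 1.12, and its interval of 0.572 to 1.77 held 1. Chromosome 4 held 75.5 regions per Mb in replicate 1 and 71.0 in replicate 2, against 44.1 and 36.6 on the autosomal arms. Coverage along chromosome 4 was highest from 500001 to 750000, at 45.0% and 42.4%, and lowest in the last window, from 1250001 to 1351857, at 7.25% and 2.54%.

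The 6 heterochromatic scaffolds (2LHet, 2RHet, 3LHet, 3RHet, XHet and YHet), which hold assembled sequence from near the centromeres and from the Y, had 47 regions in replicate 1 and 35 in replicate 2. Regions common to both replicates covered 0.473% of them, or 0.0319 times the share of the autosomal arms (95% interval 0.0216 to 0.0443). XHet, only 0.204 Mb long, held 18283 of the 43890 bp covered. It formed a single block that entered every draw unchanged, so this interval may be too narrow. The ratio depended on the list and was 0.0106 with the higher-scoring 50% of each list, 0.0425 in replicate 2 alone, 0.0547 in replicate 1 alone, 0.0612 for regions in either replicate and 0.102 in the list for the set of replicates, each with an interval below 1. XHet stood apart, with 13.7% covered in replicate 1 and 10.2% in replicate 2, whereas 3LHet was covered to 0.830% and 0.314% and 3RHet to 0.474% and 0.431%. YHet held no region in either replicate. How much of these scaffolds reads could be mapped to is not given in the sources used here, and a region that cannot be mapped cannot be called.

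**Figure D3:**
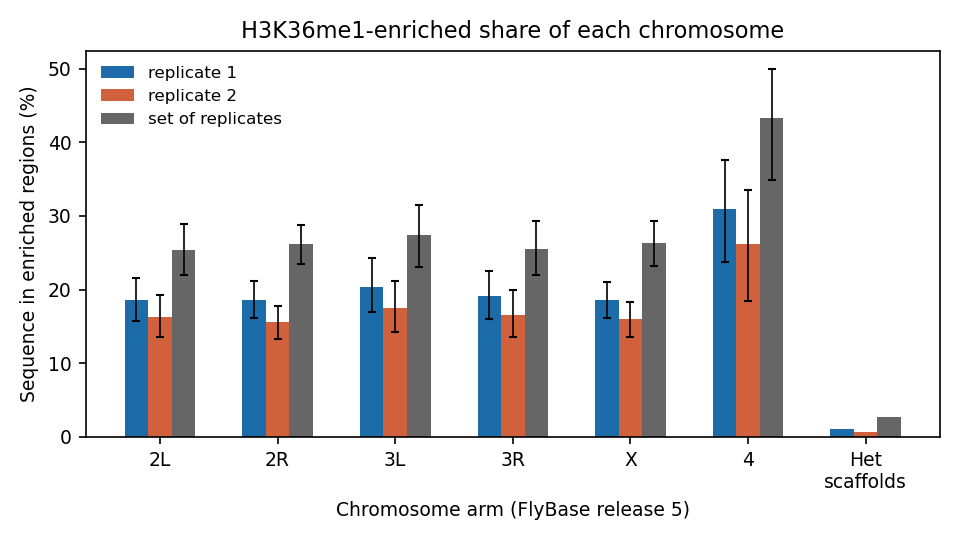
Bars give the percent of each chromosome arm's sequence in enriched regions for both replicates and the list for the set of replicates, and error bars are 95% block bootstrap intervals (1 Mb blocks, 250 kb on chromosome 4, none for the scaffolds). The large arms lie close together, chromosome 4 reaches 31.0% and 26.2% in the replicates, and the scaffolds stay at 1.05% and 0.703%.

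Regions on the X had higher scores than those on the autosomes in every list, a comparison made after the data were examined. The median score on X was 0.68 in replicate 1 and 0.81 in replicate 2, against 0.60 and 0.69 on the autosomal arms. The difference was 0.09 (95% interval 0.08 to 0.11) in replicate 1 and 0.12 (0.10 to 0.13) in replicate 2, larger than the spread among the autosomal arms. The autosomal medians lay between 0.592 on 2L and 0.599 on 2R in replicate 1, and between 0.689 on 2R and 0.698 on 3R in replicate 2. Chromosome 4 had medians of 0.57 and 0.68. In the list for the set of replicates the medians were 0.52 on X and 0.45 on the autosomal arms. The scores are the authors' own values per region, and they behave as log2 ratios.

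**Figure D4:**
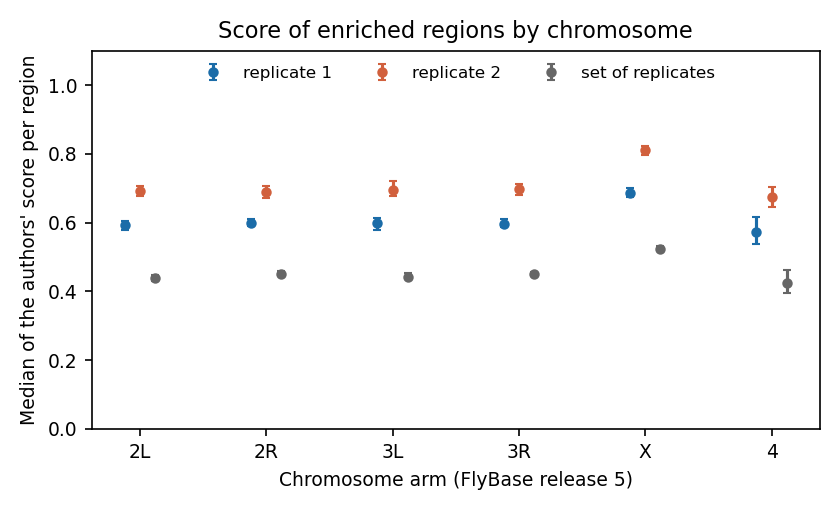
Points give the median score of the enriched regions on each chromosome arm for both replicates and the list for the set of replicates, with 95% block bootstrap intervals. The X point lies above the autosomal arms in each list, at 0.68 against 0.60 in replicate 1 and 0.81 against 0.69 in replicate 2.

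The list for the set of replicates contained almost everything called in a replicate and added many short regions, a part of which were shorter than any region of a replicate. Its shortest region was 1001 bp long, while no region of either replicate was shorter than 1301 bp. It held 8051 regions that covered 32.0 Mb, or 26.2% of the large arms. It included 99.5% of the length of replicate 1, 98.3% of that of replicate 2 and 99.99% of the shared length. Of its own length, 55.6% lay in both replicates and 21.9% in neither. Of its regions, 3122 (38.8%) overlapped both replicates, 1476 overlapped replicate 1 only and 485 overlapped replicate 2 only. The other 2968 regions (36.9%) overlapped neither replicate, with a median length of 1349 bp against 4170 bp for those that overlapped both. Their median score was 0.42 against 0.61. Of these 2968 regions, 1345 were shorter than 1301 bp. Among the 6570 set regions of at least 1301 bp, a cut chosen after the data were examined, 1623 (24.7%) overlapped neither replicate, with a median length of 1647 bp. On chromosome 4 this list covered 43.3% of the sequence, and on the heterochromatic scaffolds 2.67%.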

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

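Of 62 alternative values, 53 kept their direction and their side of the threshold or stayed within the spread used to judge them. Some of these could not move, since random placement and smaller blocks change only the p-value or the interval. The score difference in the set list was counted under both replicates. The ratio of the heterochromatic scaffolds counted as kept in every setting, though its size changed as given below. The count is therefore no measure of robustness. With the higher-scoring 50% of each list the number of regions fell by construction, to 2717 in replicate 1, 2267 in replicate 2 and 4026 in the list for the set of replicates. The overlap of the replicates passed the threshold under every alternative run for it. A reciprocal overlap of 50% lowered the matched share to 55.4% of replicate 1 and 66.6% of replicate 2, and the share of regions of the set list matched in replicate 2 from 44.8% to 34.5%. The correlation of scores rose from 0.701 to 0.821 with reciprocal pairs and to 0.791 with 1 best pair per region, and the cause was not tested. The ratio of X to the autosomal arms was 0.949, and it turned to 1.07 with the higher-scoring 50% and to 1.01 in the set list. All its intervals held 1, so no direction was called. The score cut was the median of each whole list, 0.613 in replicate 1 and 0.714 in replicate 2. The X medians (0.685 and 0.810) lay above it and the autosomal medians (0.597 and 0.694) below it. The cut therefore kept a larger share of the regions on X, and the rise to 1.07 is no separate result. The cause of the value in the set list was not tested. The ratio of chromosome 4 to the autosomal arms fell from 1.47 to 1.12 with the higher-scoring 50%, and its interval then held 1. Both intervals rest on few blocks of chromosome 4. The ratio of the heterochromatic scaffolds ran from 0.0106 with the higher-scoring 50% to 0.102 in the set list and stayed below 1. Using either replicate alone gave 0.964 to 0.967 for X, 1.58 to 1.61 for chromosome 4 and 0.0425 to 0.0547 for the heterochromatic scaffolds. The X score difference kept its direction in regions of at least 5000 bp, where it was 0.13 in replicate 1 and 0.12 in replicate 2. That setting, the length-matched one, smaller blocks and the set list for scores, and trimmed autosomal arms for chromosome 4, were added after the data were examined. No paired analysis was possible because the input samples have no values of their own and only the 2 immunoprecipitated replicates have region lists. The depth is unknown, so how far it limits the short regions, of which 38.6% of those under 2 kb in replicate 1 were matched, was not tested.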

Other observations

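The test of simple ratios on unassembled sequence, the number of regions per Mb on chromosome 4, the spacing of regions, the sequence nearest the centromeres and the choice of the X and chromosome 4 patterns came after the values had been seen. Enriched regions lay close to each other on the large arms. In replicate 1, 1137 of 5274 gaps between neighbours (21.6%) were under 1000 bp, against a mean of 5.36% and a highest of 5.99% over 100 random spacings of the same regions (one-sided permutation p = 0.0099, the smallest that 100 draws can give). In replicate 2 the share was 21.7%, against a mean of 4.36%. Random spacing is a weak comparison, since any uneven placing of regions along the arms could exceed it. The lists also cannot tell separate sites from 1 broad domain called in parts. Merging regions less than 1000 bp apart left 4266 of the 5434 regions of replicate 1. Long stretches without any region in either replicate lay on 2L from 15761813 to 16248855 (0.487 Mb), on 3L from 23732775 to 24200062 (0.467 Mb) and on 3L from 4697801 to 5143990 (0.446 Mb).

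The 10% of each arm nearest the centromere had no common direction. Regions common to both replicates covered 19.9% of it on 2L and 21.1% on 3R, against 10.1% on 2R, 7.47% on 3L and 5.81% on X. The mean over the 5 arms was 12.9%, against 14.8% for the rest of the arms, and an exact two-sided sign permutation test gave p = 0.562. With 5 arms this test cannot reach 0.05.

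The higher scores on X were weighed against 3 technical explanations, and no biological one was tested because the labels give no sexes. If fewer reads on X had only raised the score needed to pass, high scores would not be denser there. Regions above the autosomal 90th percentile were 1.43 times as dense on X in replicate 1 (95% interval 1.13 to 1.84). In replicate 2 they were 1.53 times as dense (95% interval 1.15 to 2.00). Both values argue against a raised cut as the whole cause. Fewer reads could also make scores noisier and so spread them upward, which this density cannot tell apart. Fewer reads on X therefore stay open. The 5th percentile of score was also higher on X, by 0.0839 in replicate 1 and 0.101 in replicate 2. A higher cut on X would give that, so a part played by it stays open. The 95th percentile was higher by 0.116 and 0.124. Scores on X thus lay higher at both ends, and a shift of all scores alike was not tested. After matching on region length the difference was 0.0869 in replicate 1 (95% interval 0.0766 to 0.0998) and 0.116 in replicate 2 (0.104 to 0.125), which argues against other region lengths on X. Noisier scores on X remain open as a contribution, since the correlation of replicate scores was lower on X (0.643) than on the autosomal arms (0.702), a difference of -0.0589 (95% interval -0.103 to -0.0130).

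The higher coverage of chromosome 4 could come from weaker regions that passed the threshold there. With the higher-scoring 50% of each list the ratio to the autosomal arms was 1.12 and 638 of 1826 autosomal windows were covered as much, so this explanation stays open: the ratio neither fell to 1 nor stood apart from the arms. A few very long regions are argued against as the cause by the number of regions per Mb. Chromosome 4 held 1.71 times as many as the autosomal arms in replicate 1 (95% interval 1.40 to 1.99). The ratio was 1.94 in replicate 2 (95% interval 1.43 to 2.36). These intervals rest on few 250 kb blocks and may be too narrow. Reads shared among repeats on chromosome 4 were not tested, and no biological explanation was tested.

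Of the 20 highest scores of the list for the set of replicates, 10 lay on the unplaced scaffold U. That list held 40 regions on U, 27 of them shorter than any region of a replicate list (1301 bp). The median score there was 1.38 against 0.40 for regions of the large arms no longer than the longest on U (2031 bp). Scores made of small whole numbers, which thin coverage would give, are a candidate explanation: 22 of 40 scores on U (55.0%) were ratios with a denominator of at most 10, against 130 of 3862 (3.37%) on the arms, an odds ratio of 35.1 (95% interval 17.4 to 71.0, two-sided Fisher's exact p = 1.33e-21). Among regions of at most 1200 bp the shares were 79.2% of 24 on U and 5.36% of 1045 on the arms, with median lengths of 1049 and 1070 bp and median scores of 1.65 and 0.45. Regions are not independent samples, so this p describes the list.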
